A study of Helianthus annuus with 9 samples.

How the data were processed

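Messenger RNA was profiled in roots of sunflower (Helianthus annuus) collected 15 days after sowing. There were 3 untreated libraries, 3 from roots treated with an attenuated strain and 3 from roots treated with a virulent strain. Groups and replicate numbers were taken from the sample labels. Replicates are numbered 1, 2 and 3 in the untreated group and 2, 3 and 4 in each treated group. Per the labels' protocols, RNA was extracted with the RNAprep Pure Plant kit, and libraries were made from polyadenylated RNA with the NEBNext Ultra RNA kit. The labels do not say whether the libraries of a group came from separate plants, so the p-values measure only the spread between these samples, which may be technical.

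Expression values were the FPKM (fragments per kilobase of gene and per M reads, where M stands for mega) deposited by the authors in 1 table of 60318 identifiers. The submitters' processing notes name HISAT2 2.0.4, HTSeq 0.9.1, DESeq 1.18.0 and edgeR, without giving the role of each. The genome build and annotation are not given in the sources used here. The table has no gene names or descriptions. Of its identifiers, 0 matched the gene table of the assembly HanXRQr2.0-SUNRISE, which lists 83308 genes. Genes are therefore given by identifier, the chromosome is the one stated in the identifier, and no coordinates are printed. The 38 gene lists fixed before the data were examined, which select genes by description, were not tested.

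FPKM values of a gene are whole multiples of the value of 1 read, and this step was used to recover whole reads. All values of 46579 identifiers above 0 in at least 1 library came out whole, within a relative tolerance of 1e-09 plus an absolute tolerance of 1e-05 reads. The other 13739 identifiers were at 0 in every library. A floor of 3 reads in each library was entered as a setting, and the recovery did not estimate it. A value of 0 may therefore stand for fewer than 3 reads. In data simulated for 8000 genes, the library totals were recovered exactly, as were all reads of 99.91% of genes with at least 50 reads. The recovered reads were used for depth and for an added test with limma-voom, not for the main comparisons. Library totals ranged from 19.4 to 24.8 M reads, and depth below means these totals. Recovered reads of the identifiers made up 99.97% to 99.98% of them. Reads outside these identifiers therefore cannot be seen, and sequencing depth is not known. Libraries of 1 group differed from each other by a chi-square per gene of 12.6 to 30.2, so no pair was a repeat within sampling noise.

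Genes with an FPKM of at least 1 in at least 3 libraries were tested, 30598 in all. A linear model with 1 mean per group was fitted to log2(FPKM + 1) of all 9 libraries with limma 3.58.1 in R 4.3.3, with a variance trend and no covariate. The comparisons were attenuated against untreated, virulent against untreated and virulent against attenuated. Tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. In simulated data with a dispersion of 0.03 and 100 genes changed by each fold, 4-fold changes were called in the right direction for 99% of genes in attenuated against untreated, 99% in virulent against untreated and 97% in virulent against attenuated. For 2-fold changes these shares were 63%, 54% and 71%.

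The named genes follow a rule fixed before the data were examined. For each comparison it takes the largest rises and falls among called genes with a log2 fold change of at least 1 in size and no overlap between the libraries of the compared groups. Without descriptions, the rule allows at most 2 identifiers in each direction. Reads shared with near-identical copies could not be assessed for these genes.

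The alternatives were other pseudocounts, filters, scalings, sample sets, variance models, library weights, a replicate block, a fold change minimum and each library left out in turn. Scaling without the 1000 most abundant genes and limma-voom on recovered reads were chosen after seeing the data. The shared response was set beside 100 simulated draws of unchanged groups. Each draw simulated all 9 libraries, with both treated groups set against the same simulated untreated libraries. Genes were drawn independently, so deviations that many genes of a real library share were not simulated. Neighbouring identifiers among the tested genes were compared with 100000 shuffled orders. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.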

Results

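The data are root expression profiles of sunflower from 3 groups of 3 libraries. Plants were untreated, treated with an attenuated strain or treated with a virulent strain, and roots were taken 15 days after sowing. The study concerns cross-protection, in which a fungus of low virulence (here Gibellulopsis nigrescens Vn-1) lessens Verticillium wilt, a vascular disease. The labels do not name the strain used in each group or the time between treatment and sampling. Sample titles carry a number of unstated meaning that is 2 in the untreated group and 1 in both treated groups, so any effect of it cannot be separated from treatment in the comparisons with untreated roots. Depth in reads of the listed identifiers was similar across groups, at 21.3 ± 3.0 M reads (SD, n = 3) in untreated, 21.0 ± 2.57 in attenuated and 20.7 ± 0.7 in virulent libraries. Genes with at least 10 reads numbered 33439 ± 356 (SD, n = 3) in untreated, 32672 ± 584 in attenuated and 32058 ± 127 in virulent libraries. The 1000 genes with most reads in each library held 33.4% ± 0.289 of reads (SD, n = 3) in untreated, 35.3% ± 0.6 in attenuated and 37.0% ± 0.351 in virulent libraries.

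The groups were separated in a principal component analysis of the tested genes. The first component held 45.5% of the variance. On it, untreated libraries lay between -56.1 and -48.6, attenuated libraries between -0.2 and 23.3, and virulent libraries between 26.5 and 51.3. The second component held 15.7% and placed the attenuated libraries, at 23.2 to 32.0, above all libraries of the other groups.

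**Figure D1:**
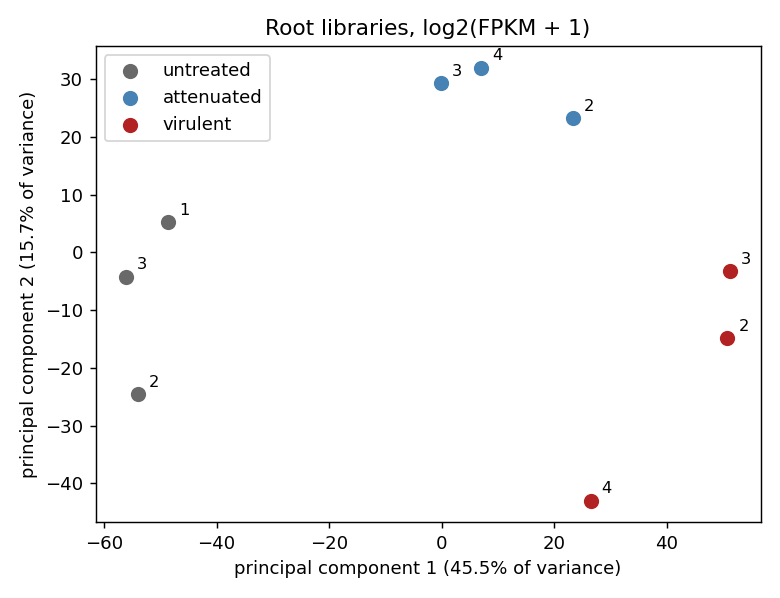
Principal components 1 and 2 of log2(FPKM + 1), in component units, with 1 point per library, coloured by group and numbered by replicate. The untreated libraries sit at or below -48.6 on component 1, and the attenuated libraries sit at or above 23.2 on component 2.

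Treatment with the attenuated strain was compared with no treatment to find how the roots of these groups differed. The control is labelled as wild-type without treatment, and no mock treatment is among the groups. In both comparisons with untreated roots, effects of a strain and of its application therefore cannot be told apart. HannXRQ_Chr04g0119001 on chromosome 4 fell from an FPKM of 250 ± 53.8 to 12.6 ± 2.5 (SD, n = 3), a log2 fold change of -4.20 ± 0.28 (SE; limma adjusted p = 3e-04). It was also called lower in virulent than in untreated roots, at -2.81 ± 0.28 (SE; limma adjusted p = 0.000968). HannXRQ_Chr11g0323881 on chromosome 11 fell from 53.1 ± 12.2 to 2.59 ± 1.2 (SD, n = 3), a log2 fold change of -3.95 ± 0.28 (SE; limma adjusted p = 0.000332). In virulent against untreated roots its log2 fold change was -2.74 ± 0.28 (SE; limma adjusted p = 0.00102). HannXRQ_Chr03g0060761 on chromosome 3 rose from 6.25 ± 1.42 to 106 ± 118 (SD, n = 3), a log2 fold change of 3.32 ± 0.61 (SE; limma adjusted p = 0.0184). It was also called higher in virulent than in untreated roots, at 3.50 ± 0.61 (SE; limma adjusted p = 0.00539). Its attenuated libraries were at 243, 41.0 and 34.8, the log2 fold change was 2.44 without attenuated replicate 2, and among libraries left out the call was lost without untreated replicate 1 or 3, at limma adjusted p of 0.0539 and 0.0665. HannXRQ_Chr15g0489011 on chromosome 15 had 3 reads in untreated replicate 1 and 0, which may stand for fewer than 3, in the other untreated libraries. The attenuated libraries had 1165, 244 and 25 reads. Per total reads this is a ratio of 484, with an exact 95% interval of 165 to 2352 that covers counting error only. This and the next ratio take the untreated values of 0 as 0 reads, and would be lower if reads lay under the floor of 3. Without attenuated replicate 2, which held 1165 of the reads, the ratio was 131 (exact 95% interval 44 to 641). Its log2 fold change was 4.27 ± 1.03 (SE; limma adjusted p = 0.0467). This call was lost in 12 of 22 alternatives, among them leaving out untreated replicate 1, 2 or 3, attenuated replicate 2 or 3, or virulent replicate 2 or 3, and its limma-voom value was 7.64 with an adjusted p of 0.381. The log2 fold change was 3.01 without attenuated replicate 2 and 5.55 without attenuated replicate 4.

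Of 30598 genes tested, limma called 1744, of which 362 rose and 1382 fell. Changes over 2-fold made up 129 of the rises and 629 of the falls. The share of called genes that fell was 79.2%, and it was 62.4% after quantile normalization. All libraries of 1 group lay above all of the other for 31.2% of genes, where chance gives 10%. Every library taken out of these groups changed the count by over 1.5 times: 1132, 913 and 704 genes without untreated replicate 1, 2 or 3, and 628, 771 and 1025 without attenuated replicate 2, 3 or 4.

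Treatment with the virulent strain was compared with no treatment in the same way. HannXRQ_Chr11g0351581 on chromosome 11 rose from an FPKM of 10 ± 6.92 to 297 ± 140 (SD, n = 3), a log2 fold change of 4.94 ± 0.62 (SE; limma adjusted p = 0.00168), which was 4.18 without untreated replicate 1. It was also called higher in attenuated than in untreated roots, at 2.58 ± 0.62 (SE; limma adjusted p = 0.0473). Between the treated groups it was not called (limma adjusted p = 0.0869). HannXRQ_Chr15g0489011, nearly without reads in untreated roots, had 422, 352 and 147 reads in the virulent libraries. Its ratio per total reads was 316, with an exact 95% interval of 108 to 1537 for counting error only, again taking untreated values of 0 as 0 reads. Its log2 fold change was 4.70 ± 1.03 (SE; limma adjusted p = 0.0126). That call was lost without virulent replicate 2 and with limma-voom, where the log2 fold change was 8.20 and the adjusted p 0.245. HannXRQ_Chr03g0061911 on chromosome 3 fell from 52.1 ± 8.63 to 2.72 ± 1.52 (SD, n = 3), a log2 fold change of -3.90 ± 0.45 (SE; limma adjusted p = 0.00131). HannXRQ_Chr03g0085865, also on chromosome 3, fell from 28.9 ± 10.1 to 3.17 ± 5.49 (SD, n = 3), a log2 fold change of -3.72 ± 0.79 (SE; limma adjusted p = 0.0112). It rests on few reads, with 42, 18 and 20 in untreated and 0, 0 and 8 in virulent libraries, where 0 may stand for fewer than 3. Its log2 fold change was -4.85 without virulent replicate 4, -5.93 with a pseudocount of 0.1 and -2.21 with a pseudocount of 5.

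The virulent comparison had 7156 called genes in limma, 23.4% of those tested, with 2099 higher and 5057 lower. Changes over 2-fold comprised 378 rises and 1566 falls. The direction of the smaller changes depended on the scaling: 70.7% of called genes fell with FPKM as deposited, 55.6% after median-ratio scaling and 45.1% after quantile normalization, which moved the median log2 fold change of all genes from -0.078 to 0.062. Among changes over 2-fold, falls made up 80.6% as deposited, 75.1% after median-ratio scaling and 70.1% after quantile normalization. The groups did not overlap for 40% of genes, where chance gives 10%. The count was 4287 without untreated replicate 3 and 3871 without virulent replicate 2.

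The differences of both treated groups from untreated roots were then set side by side. Genes called higher in both treatments numbered 284, against 24.8 for independent lists. Genes called lower in both numbered 1247, against 228.4. Simulated unchanged groups gave 0 for both counts, which carries no information on the overlap because no effect was simulated. Of the genes called in attenuated roots, 87.8% were called in the same direction in virulent roots. Across genes, which are not independent replicates, fold changes had a correlation of 0.76, where simulated unchanged groups sharing untreated libraries gave 0.5. Their covariance was 0.173 against a simulated 0.025, a difference of 0.148. The 3 untreated libraries cannot be split into parts of at least 2, so part of the excess may come from the shared controls. Across all tested genes, the attenuated change was 62.5% of the virulent change per unit. This was computed after subtracting from the covariance and the variance the parts that the average spread between libraries gives, the shared untreated libraries included. Genes called the same way in both treatments, 1531 in all, numbered 959, 819 and 646 without untreated replicate 1, 2 or 3, and 591, 726 and 914 without attenuated replicate 2, 3 or 4. Of the 1531, 270 higher and 1208 lower genes were not called between the treated groups. Their median log2 fold changes were 0.77 and -0.97 in attenuated and 0.84 and -1.05 in virulent roots. These genes had to pass in both comparisons, which favours large attenuated changes.

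**Figure D2:**
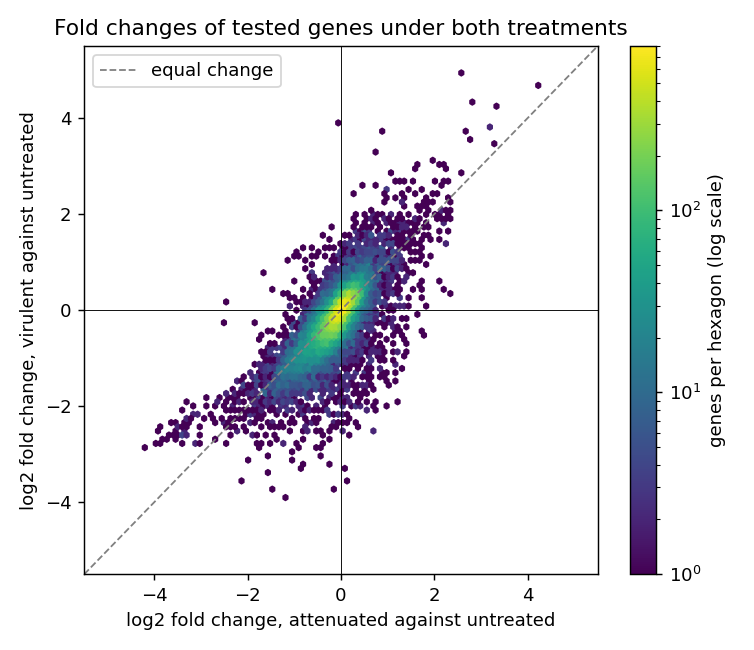
Log2 fold change against untreated in attenuated roots (x axis) and virulent roots (y axis) for the 30598 genes tested, coloured by genes per hexagon on a log scale, with a dashed line at equal change. The correlation across genes was 0.76, where simulated unchanged groups sharing untreated libraries gave 0.5.

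The treated groups were compared directly to find genes that told the virulent strain from the attenuated one. HannXRQ_Chr03g0074541 on chromosome 3 was nearly lost in attenuated roots alone among the 3 groups: its FPKM was 5.19 ± 1.12 in untreated, 0.129 ± 0.223 in attenuated and 6.08 ± 1.23 in virulent roots (SD, n = 3). Its log2 fold change, virulent against attenuated, was 2.65 ± 0.20 (SE; limma adjusted p = 0.00219), and attenuated against untreated it was -2.46 ± 0.20 (SE; limma adjusted p = 0.000604). Its attenuated libraries had 0, 9 and 0 reads, where 0 may stand for fewer than 3. HannXRQ_Chr17g0549691 on chromosome 17 was at 4.63 ± 2.13 in attenuated and 39.8 ± 12.5 in virulent roots (SD, n = 3), a log2 fold change of 2.88 ± 0.41 (SE; limma adjusted p = 0.0139). HannXRQ_Chr07g0191171 on chromosome 7 was at 65.8 ± 31.5 in untreated and 65.9 ± 11.6 in attenuated roots, and at 6.41 ± 5.87 in virulent roots (SD, n = 3). Its log2 fold change, virulent against attenuated, was -3.44 ± 0.53 (SE; limma adjusted p = 0.0166), and -4.05 without virulent replicate 2. HannXRQ_Chr14g0461931 on chromosome 14 was at 70.1 ± 21.7 in attenuated and 7.91 ± 9.05 in virulent roots (SD, n = 3), a log2 fold change of -3.53 ± 0.74 (SE; limma adjusted p = 0.0433), which was -4.38 without virulent replicate 2 and -2.71 without virulent replicate 3. This last call was lost in 15 of 22 alternatives, among them leaving out any attenuated library, untreated replicate 1 or 3, or virulent replicate 3 or 4. Over all 22, the limma adjusted p ranged from 0.0274 to 0.165.

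Between the treated groups limma called 848 genes, 223 higher and 625 lower in virulent roots. Over 2-fold there were 91 higher and 301 lower. Of the 848, 168 were higher and 526 lower in virulent roots than in both other groups without being called between attenuated and untreated roots. The count of 848 depended on single libraries: it was 16 without attenuated replicate 3, 48 without attenuated replicate 4, 435 without attenuated replicate 2, 224 without virulent replicate 2 and 301 without virulent replicate 4. The calls of HannXRQ_Chr17g0549691 and HannXRQ_Chr07g0191171 were also lost without attenuated replicate 3 or 4, at adjusted p of 0.0699 and 0.0514 for the first and 0.0794 and 0.0634 for the other in limma. The first was lost without virulent replicate 2 (limma adjusted p = 0.0512) and the other without virulent replicate 4 (limma adjusted p = 0.0541).

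**Figure D3:**
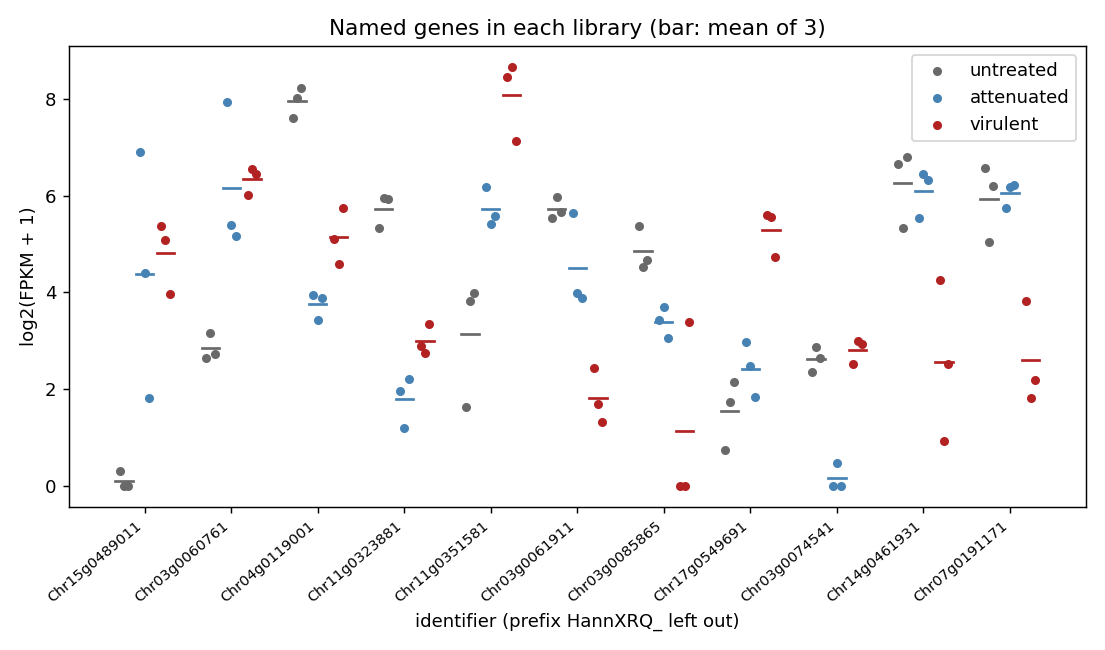
Expression of the named genes as log2(FPKM + 1) in each of the 9 libraries, with 1 point per library and a bar at the mean of 3. HannXRQ_Chr03g0074541 is at an FPKM of 0.129 in attenuated roots and at 5.19 and 6.08 in untreated and virulent roots.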

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

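Scaling without the 1000 most abundant genes and limma-voom on recovered reads were chosen after seeing the data, and the other alternatives before. All 263 values of the 12 named results kept their direction, 6 of the 12 kept every call and 39 calls were lost. The genes were chosen from these data as large changes without overlap between groups, so the kept directions say little about stability. Counts that moved by over 1.5 times follow, and except where fewer genes or samples entered, the cause was not tested. For attenuated against untreated, the count was 1098 (802 lower) with a mean FPKM of at least 5, 2641 (642 higher) with library weights and 758 (129 higher, 629 lower) with a fold change minimum of 2-fold, and quantile normalization gave 673 higher. For virulent against untreated, genes higher numbered 3234 with median-ratio scaling, 4076 with quantile normalization (3344 lower), 3230 without the 1000 most abundant genes and 3305 with library weights. A mean FPKM of at least 5 gave 3273 lower, and the fold change minimum gave 1944 (378 higher, 1566 lower). For virulent against attenuated, the count was 411 (92 higher, 319 lower) without a filter, 1969 (614 higher, 1355 lower) with library weights and 392 (91 higher, 301 lower) with the fold change minimum. Quantile normalization gave 392 lower, and only the 6 libraries compared gave 128 higher. Genes called the same way in both treatments numbered 969 with a mean FPKM of at least 5 and 611 with the fold change minimum. limma-voom called 1760, 7097 and 678 genes in the 3 comparisons, of which 1600, 6790 and 652 were also called in the same direction on FPKM.

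Leaving out 1 library gave 628 to 2128 genes for attenuated against untreated (99 to 455 higher, 529 to 1673 lower), 3871 to 7204 for virulent against untreated (924 to 2055 higher, 2947 to 5196 lower) and 16 to 854 for virulent against attenuated (6 to 224 higher, 10 to 647 lower). Genes called in both treatments ranged from 591 to 1843, and the attenuated change per unit of virulent change from 55.2% to 68.1%.

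With the replicate block, the counts were 614 (117 higher, 497 lower), 2964 (701 higher, 2263 lower), 163 (37 higher, 126 lower) and 546 in both treatments. The block ended the calls of HannXRQ_Chr03g0060761 for attenuated against untreated (limma adjusted p = 0.0806) and of HannXRQ_Chr07g0191171 (0.0824) and HannXRQ_Chr14g0461931 (0.165) for virulent against attenuated, and of no other named gene. Named folds of genes with low values also moved with the pseudocount: HannXRQ_Chr03g0074541, virulent against attenuated, had a log2 fold change of 5.17 with a pseudocount of 0.1, 1.11 with 5 and 6.42 with limma-voom. Same-numbered libraries correlated in their deviations between -0.26 and 0.22 over 7 pairs, and others between -0.22 and 0.33. The same-numbered pairs thus did not correlate more than the others. With 3 libraries per group this cannot exclude that the numbers pair the samples. Alternatives for the 38 gene lists were not run, because the lists themselves were not tested.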

Other observations

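Median-ratio scaling and quantile normalization were planned before the data were examined, but what they would show about the falls was set down only after the result was seen. Scaling without the 1000 most abundant genes and the tests of depth, of title numbers, of chance order and of other sample splits were chosen only after the result was seen; the test of neighbour length was not. The attenuated group also had changes of its own. Among genes not called between virulent and untreated roots, 23 were higher in attenuated roots than in both other groups, with a median log2 fold change of 1.24 against untreated and -0.19 for virulent against untreated, and 13 were lower, with medians of -1.04 and 0.12. A further 11 genes were lower in both treatments and lower still in attenuated roots, with medians of -3.33 in attenuated and -2.12 in virulent roots. These sets rest on the virulent against attenuated calls, which numbered 16 without attenuated replicate 3.

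Summed FPKM of the 66 identifiers with a mitochondrial prefix was 94.7 ± 5.98 (SD, n = 3) in untreated, 46.9 ± 9.03 in attenuated and 36.7 ± 4.48 in virulent roots. These identifiers held only 0.0205% of reads in untreated, 0.00841% in attenuated and 0.00603% in virulent libraries, which were made from polyadenylated RNA. Of the 8 that were tested, 1 was called lower in attenuated and 2 in virulent roots against untreated, and 0 were called higher. The median log2 fold change of the 8 was 0.01 in attenuated and -0.19 in virulent roots. Identifiers with neither a chromosome nor an organelle prefix, 1079 of those tested, were called less often than genes on numbered chromosomes, with an odds ratio of 0.53 (95% interval 0.36 to 0.75; Fisher's exact test adjusted p = 0.000206 over 3 tests) for attenuated and 0.74 (0.63 to 0.87; adjusted p = 0.000206) for virulent against untreated. For virulent against attenuated the odds ratio was 1.04 (0.7 to 1.49; Fisher's exact test adjusted p = 0.85). Genes are not independent, so these p-values are too small. Abundance was ranked by mean FPKM over all 9 libraries, treated ones included, so the ranks partly depend on the changes. Genes that rose are favoured among the most abundant, and genes that fell among the least abundant. Among the 1000 most abundant genes, 188 rose and 87 fell in virulent roots with FPKM as deposited, 274 and 74 after median-ratio scaling and 150 and 143 after quantile normalization. In attenuated roots 33 of them rose and 30 fell as deposited, and 28 and 45 after quantile normalization. Among the 15598 least abundant genes, 568 rose and 2574 fell in virulent roots as deposited, and 1631 and 1407 after quantile normalization. In attenuated roots these numbers were 87 and 730, and 202 and 561.

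More genes fell than rose in both treatments. In attenuated roots, scaling of the FPKM values left at least 62.4% of called genes lower under 3 other scalings, which argues against scaling as the whole cause. Without untreated replicate 1, the deepest of its group, the treated groups were the deeper on average, at 21.0 and 20.7 M reads against 19.6, and 79.1% of called genes in attenuated and 73.3% in virulent roots were lower, which argues against depth. In virulent roots, quantile normalization left 45.1% of called genes lower, so for changes of any size a scaling effect cannot be told apart from a fall in expression. For changes over 2-fold in virulent roots the share was at least 70.1% under the same scalings, and a lower expression of many genes in treated roots stays open.

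Sample titles carry the number 2 after the group letter in untreated libraries and 1 in both treated groups, and its meaning is not given in the sources used here. The 1531 genes called the same way in both treatments cannot be told apart from a difference that follows this number, because it follows treatment completely. It does not separate the treated groups, between which 848 genes were called. Treatment stays an open explanation for the difference from untreated roots.

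Tested genes with neighbouring identifiers on a chromosome tended to change together. Places were counted over tested genes only, so untested identifiers may lie between neighbours. The correlation of fold changes between next neighbours was 0.071 in attenuated and 0.087 in virulent roots against untreated and 0.1 between treated groups, above all shuffled orders (permutation adjusted p = 1e-05 each over 9 tests, the smallest they can give). At 10 places apart it was 0.0, 0.0 and 0.003. For neighbours over 1.5 times apart in length it was 0.025, 0.054 and 0.071, and for the others 0.14, 0.136 and 0.144. Reads shared between near-identical copies may therefore contribute. In none of the comparisons can they be told apart from joint regulation, because a difference in length does not exclude shared reads. Among neighbours over 1.5 times apart in length, 0.054 and 0.071 lay above all shuffled orders. For the attenuated comparison, 0.025 lay below the highest shuffled value of 0.033 (permutation adjusted p = 0.0004). This 0.025 is also within sampling error (0.0075) of the bound of 0.02 set in advance.

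For each comparison, the 6 libraries make 10 splits into groups of 3, too few for a share under 0.05. In each, 1 split, the real one, gave as many genes. The real counts were 1744 for attenuated against untreated, 7156 for virulent against untreated and 848 for virulent against attenuated, and the highest of the other splits gave 1, 0 and 25. Every other split mixes the compared groups, which adds their difference to the spread within each part. Low counts there therefore do not measure false calls.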
